A study of Drosophila melanogaster with 3 samples.

How the data were processed

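Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos aged 0 to 24 h that expressed a CG7963-eGFP fusion, with an antibody against GFP, per the labels. Chromatin was sonicated to a size range of 200 to 800, per the labels, which give no unit. There were 3 biological replicates of 1 group, numbered as in the labels, and no replicate's peak list was identical to another's. A control experiment is named in the labels and was used by the authors upstream; control samples were not analysed here, so no peak could be compared with the same locus in embryos without the tag.

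The authors deposited 7 ranked peak lists and 7 thresholded sets, all in assembly dm6. Per the descriptions deposited with them, each replicate's lists came from its own alignments and a control, and the series-level lists from all 3 replicates. The thresholded sets drew on an additional file whose role is not stated. The aligner, the peak caller, their versions and the threshold on irreproducibility are not given in the sources used here. The score of a peak, as the authors deposited it, is a scaled IDR (irreproducible discovery rate) score, higher for peaks found more reproducibly. The lowest score in any thresholded set was 830. The signal, as the authors deposited it, is the peak caller's own value per peak and was used only within 1 list. Summit positions were taken from the lists. Each thresholded set was paired with the ranked list that held all of its peaks with the same score and signal. Read depth is unknown, because the lists hold peaks only, so no interval or detection limit that needs depth was computed. Every peak on a chromosome arm ended within the length of that arm in the reference.

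Gene positions came from Ensembl annotation release 115 and sequences from the RefSeq copy of the same assembly. Transposable elements were left out as genes. Of 18277 other genes, those with a ranked or thresholded summit within 500 bp of a TSS were testable (15231 for the conservative set). The conservative set was the main set, as the only series-level set whose name gives its role. The background was the ranked list that contains it, less its own peaks; 0.453% of the background summits lay within 500 bp of a conservative summit. Summits were assigned to promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, intron or intergenic sequence, in that order. Noncoding exons and sequences outside the arms were added as classes after the plan was written, since the planned classes had no place for them, and p-values were adjusted over all 8. Sequences outside the arms could not be matched by name to the reference, so 28 conservative peaks were left out of promoter, motif and gene tests.

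Overlap of peaks needed at least 1 bp and was compared with 1000 random placements on the same chromosomes. Odds ratios have 95% intervals from the standard error of their logarithm, with 0.5 added to each cell where 1 was empty, and p-values from two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family. For motifs (100 bp on each side of the summit) and 7-mers (50 bp), 10 background peaks were drawn per peak with the same promoter share; set C allowed 8, and the set of replicate 3 alone allowed 9. Differences in median signal were tested by 100000 permutations. The code for lists was tested on simulated genes, and that for 7-mers on background windows. A 7-mer written into 10% of 1200 such windows ranked first of 8192. For classes and motifs, random parts of the background were compared, with 0 calls. No effect was planted there, so recovery was not tested for them. Of 100 simulated lists of 60 genes at 3 times the odds, 82 were recovered, and 12 of 2000 unchanged lists were called.

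The sample groups, tests, 21 gene lists, 14 motifs, the alternatives (other overlap rules, other sets, backgrounds and windows, and leaving out each replicate) and the rule for named genes were chosen before the data were examined. The symbols nos and SA could not be matched to a single gene and were left out of their lists. The rule names CG7963; the gene with the nearest TSS for each of the 20 conservative peaks of highest signal found in all 3 replicates; and, for each list, up to 4 members with the highest-signal peak within 500 bp of a TSS. Stck, Atg13, Ibf2 and tRNA:Gly-GCC-1-13 are named outside the rule, as neighbours, after their values were seen. Random draws from the ranked lists, tRNA genes counted by peak, and tests without peaks of signal under 20 were added after seeing the data. The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.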

Results

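The series measured where a tagged protein sat on the genome of whole fruit fly embryos collected 0 to 24 h after egg laying. The embryos carried CG7963 fused to the green fluorescent protein eGFP. Chromatin was precipitated with an antibody against GFP and the recovered DNA was sequenced (ChIP-seq). There was 1 group of 3 biological replicates and therefore no comparison between conditions. The values were peak lists in dm6 coordinates, so the read depth of each sample is unknown. The thresholded sets held 1680 peaks in replicate 1, 1494 in replicate 2 and 1800 in replicate 3, a mean of 1658 ± 154 (SD, n = 3). The authors' conservative set, made from all 3 replicates, held 2499 peaks with a median width of 320 bp. It came from a ranked list of 154041 peaks, of which the 151542 outside the conservative set served as background. Other series-level sets, called A, B and C here in order of size, held 2298, 2369 and 3351 peaks.

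The first question was whether the gene of the tagged protein itself carried a peak. CG7963 (FBgn0037584) is a gene on chromosome 3R, from 8362826 to 8363894 on the plus strand. No thresholded set held a peak over the gene, in the series-level sets or in any of the 3 replicates. The strongest ranked peak over it in the conservative set's list spanned 8363403 to 8363722, with a signal of 51.3 and rank 9771 of 154041. The conservative set held 4 peaks within 20 kb, where the mean over all genes was 1.33. The peak 42 bp from the TSS of stck had a signal of 170 and that 32 bp from the TSS of Atg13 had 163. The others, with signals of 99.3 and 90.9, had CG7963 as the nearest TSS at 5676 and 14983 bp. The first of these was found in no replicate's thresholded set.

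The replicates were compared to see how far the same sites were recovered. Of the 2499 conservative peaks, 1083 (43.3%) were overlapped by a thresholded peak in all 3 replicates, and 481 (19.2%) in none. Random placement of the replicate sets on the same chromosomes gave at most 1 such peak in 1000 placements (one-sided permutation p = 0.001, the smallest possible). Between replicates, 73.8% ± 5.19 of a set's peaks (SD over the 6 directed pairs, which are not independent) were overlapped in another. The lowest share was 66.7% of replicate 3 in replicate 2, and the highest was 79.7% of replicate 2 in replicate 3. Random draws from the other replicate's ranked list, of as many peaks as its thresholded set held, reached at most 3.21% in any pair. The conservative set was made from the same reads, so the pairwise shares are the more separate measure.

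**Figure D1:**
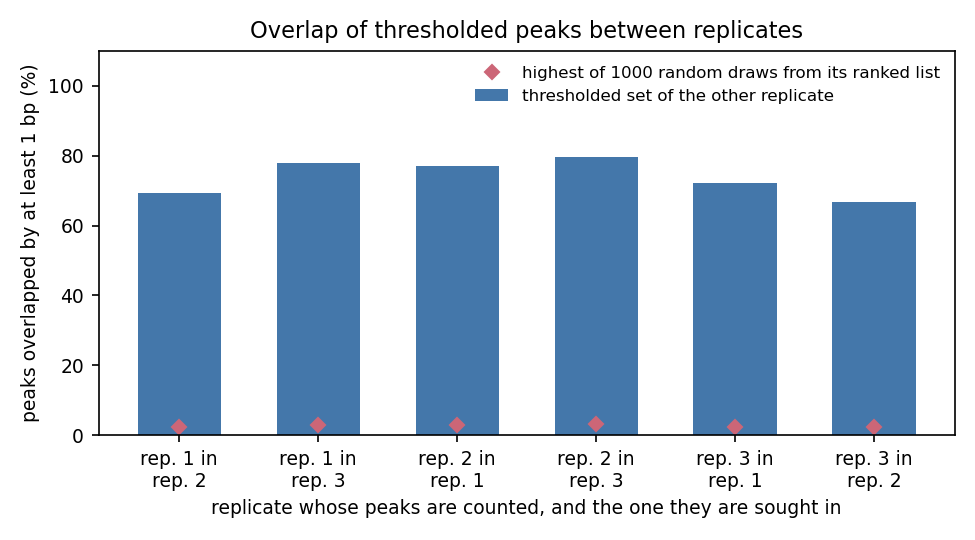
Bars give the share of each replicate's thresholded peaks, in percent, that were overlapped by at least 1 bp in another replicate, for the 6 directed pairs. Diamonds give the highest share in 1000 random draws from the other replicate's ranked list; the bars lie between 66.7% and 79.7% and the diamonds at or below 3.21%.

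Peaks found in all 3 replicates had a higher signal than the rest of the conservative set. Their median signal was 220, against 95.4 for the other 1416 peaks, a difference of 124.6. This direction is expected, since the signal comes from the same reads as the replicate sets and a strong peak passes in each replicate more easily, so the difference describes the sets and is not evidence of reproducibility. The signal is the peak caller's own value per peak, as deposited.

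The strongest peaks lay mostly at promoters. Of the 20 peaks of highest signal that all 3 replicates shared, 18 had a summit within 500 bp of an annotated TSS. The strongest of all, with a signal of 1540, spanned 8452215 to 8452516 on X inside an intron of org-1 (FBgn0021767), which encodes a T-box transcription factor. Its summit lay 2505 bp from the nearest TSS, and no CGATA was found within 100 bp of it. The sequence at this summit holds TGGTTAAAGTG more than once, and any effect of that repeat on the signal was not tested. The second, with a signal of 1203, lay 73 bp from the TSS of MESK2 on 2R (21501909 to 21502160). The third, at milt on 2L (7049026 to 7049275), a gene for an adaptor in mitochondrial transport, had a signal of 972.3. The ubiquitin ligase gene Ube3a followed with a signal of 890.5 at 53 bp, and Rpn6, which encodes a proteasome lid subunit, with 851.8 at 91 bp. Signals were 838.4 at Capr, 826.5 at the ribosomal protein gene RpL32, 741.3 at the adducin gene hts and 725.8 at CG11030. The atypical cadherin gene kug had a signal of 710.6, Fit2 702.3, jagn 689.9, Daxx 689, Pym 680.2 and Sumo 679.8. The remaining peaks were at CG9135 (672.5), the zinc transporter gene foi (669.1), the succinyl-CoA synthetase gene Scsalpha1 (661), ArgRS (633.5) and CG2924 (628.4). The peak named for ArgRS, an aminoacyl-tRNA synthetase gene on X, was intergenic and 2559 bp from the nearest TSS. At least 1 CGATA lay within 100 bp of every summit among the 20 except those at org-1 and milt.

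Summits were concentrated at promoters. Of the 2471 conservative peaks on assembled arms, 2129 (86.2%) had a summit within 500 bp of a TSS, against 14.4% of 149146 background peaks. The odds ratio was 37.1 (95% interval 33.1 to 41.6, Fisher's exact test, p smaller than the software can write). The median distance to a TSS was 52 bp, against 2822 bp in the background. In sets of single replicates the promoter share was 90.4%, 88.6% and 90.9%. The odds ratio was 115.5 among peaks found in all 3 replicates, 20.4 in set C, and from 93.4 to 99.1 among peaks shared by both other replicates when each was left out in turn.

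Gene bodies and intergenic sequence held few summits. The classes divide a common total, so the promoter excess alone lowers the other shares. A lower share is therefore not by itself a separate finding. Introns outside promoters held 5.84% of conservative and 36.5% of background peaks (odds ratio 0.108). Intergenic sequence held 4.60% and 23.2% (0.160), and coding exons 1.92% and 19.7% (0.0797). The shares were 0.92% and 3.07% for 3' UTRs (0.294), 0.24% and 0.934% for 5' UTRs outside promoters (0.255), and 0.16% and 0.802% for noncoding exons (0.198). All 7 annotated classes, promoters included, differed from the background by Fisher's exact test, with Benjamini-Hochberg adjusted p of at most 5.54e-05. In set C the share in 5' UTRs did not (adjusted exact p = 0.190). Among peaks shared by both other replicates introns and coding exons were rarer still: without replicate 1, 2 or 3 the odds ratio of introns was 0.0474, 0.0469 and 0.0459, and coding exons held 1, 0 and 1 summits. Annotated transposable elements held 42 conservative summits (1.68%) and 1.59% of the background (odds ratio 1.06, Fisher's exact p = 0.686).

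**Figure D2:**
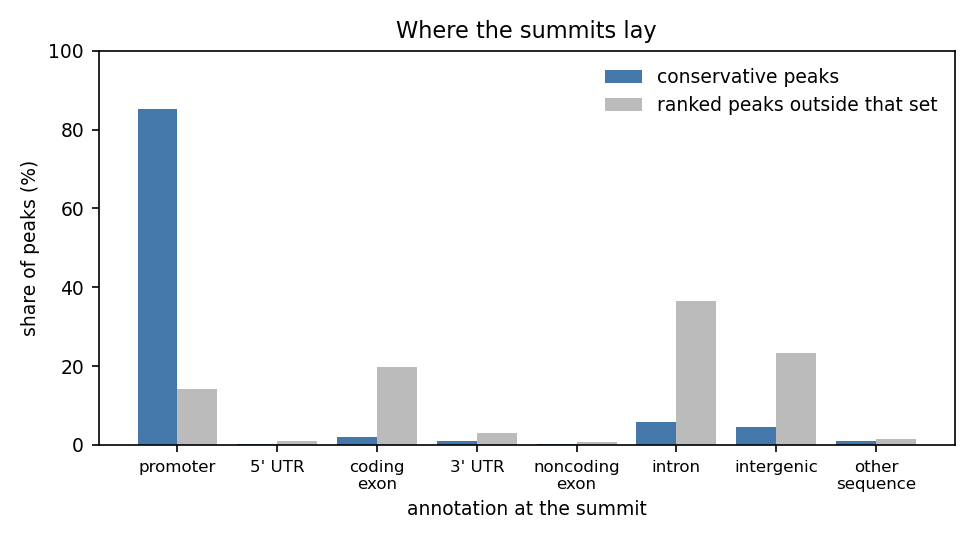
Bars give the share of peaks, in percent, whose summit lay in each annotation class, for the 2499 conservative peaks and the 151542 ranked peaks outside that set. Promoters (within 500 bp of a TSS) held 85.2% of the conservative and 14.1% of the other peaks.

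Most chromosome arms held close to their share of the background peaks. Arm 2R held 516 conservative peaks (20.6% against 18.4% of the background; odds ratio 1.15, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.0199). Arm 3L held 450 (18.0% against 19.8%; 0.888, adjusted exact p = 0.0455), a call lost in set A (0.0501) and set C (0.693). Chromosome 4 held 14 (0.56% against 0.265%; 2.12, adjusted exact p = 0.0268), and the Y held 0, against 440 background peaks (odds ratio 0.0686, 95% interval 0.00428 to 1.10, adjusted exact p = 0.0142). Arms 2L, 3R and X, with odds ratios of 1.04, 0.916 and 1.08, did not pass the test, although X did in each replicate's own set (odds ratios of 1.18, 1.22 and 1.30), among peaks in all 3 replicates (1.26, adjusted exact p = 0.00976), in set B (1.13, 0.0394), without replicate 1 (1.27, 0.00448) or 3 (1.23, 0.0171) and in the stronger conservative peaks, those above the median signal (1.22, 0.0107), and 3R did in set C (0.904, 0.0237) and in replicate 2's own set (0.856, 0.0271). Against random genomic positions chromosome 4 had an odds ratio of 0.538, in the opposite direction. Among peaks shared by both other replicates, chromosome 4 had odds ratios of 0.939 without replicate 1, 1.70 without replicate 2 and 1.29 without replicate 3, and neither it nor the Y passed (adjusted exact p of 0.206 or more and of 0.0598 or more). Nor did either among peaks in all 3 replicates (0.780 and 0.132, exact) or in the stronger peaks (0.452 and 0.0908).

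The sequence CGATA, the core bound by the insulator protein BEAF-32, was the most common of the 14 motifs fixed in advance that were richer at summits. It lay within 100 bp of 1830 of 2471 summits (74.1%), against 24.1% of background peaks with the same promoter share (odds ratio 8.99, 95% interval 8.18 to 9.88). The odds ratio was 5.75 in set C, 18.6 among peaks in all 3 replicates, and 16.6, 18.4 and 16.1 without replicate 1, 2 or 3. The DNA replication-related element TATCGATA, bound by Dref, was present at 678 summits (27.4%) against 1.20% (odds ratio 31.1, 26.9 to 35.9). It contains CGATA, so these summits are among the 1830. Both p-values of Fisher's exact test were smaller than the software can write. CGATA matches peaked at the summit, with 46.9 matches per 100 windows in the 25 bp after it against 4.22 in the background.

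**Figure D3:**
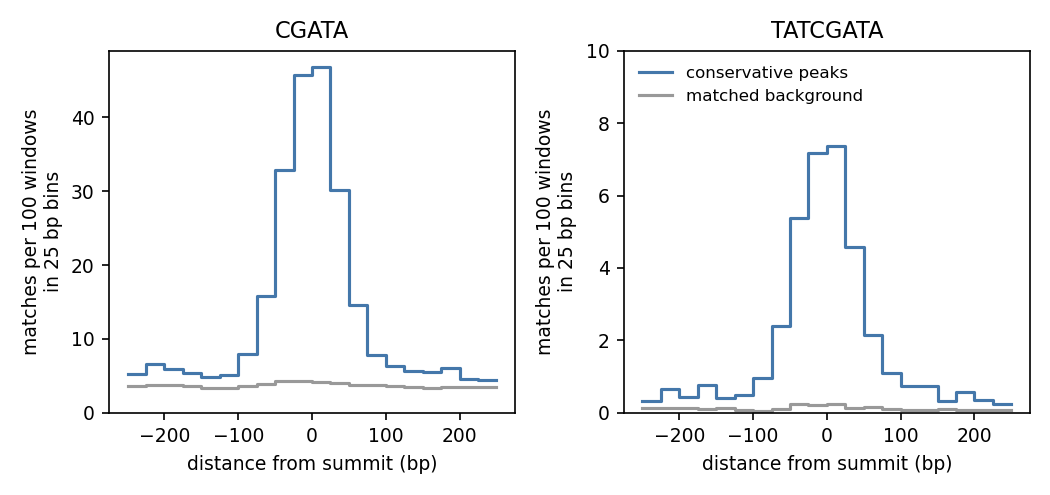
Lines give the number of matches on either strand per 100 windows in bins of 25 bp, by distance from the summit in bp, for CGATA and TATCGATA in 2471 conservative and 24710 matched background peaks. The conservative line rises to 46.9 for CGATA and 7.37 for TATCGATA at the summit.

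Other core promoter motifs were also more frequent. The background was drawn to match the promoter share of the peaks, not their distance to a TSS. Before that draw, 47.1% of conservative summits on the arms lay within 50 bp of a TSS, against 2.05% of background summits. How far closeness to a TSS accounts for the excess of these motifs, of CGATA and TATCGATA, and of the 7-mers below was not tested. Ohler motif 7 was found at 17.2% of summits against 2.79% (odds ratio 7.22), motif 1, bound by M1BP, at 5.22% against 0.935% (5.84), and motif 6 at 1.01% against 0.303% (3.36). The E-box form CAGCTG was found at 14% against 11.6% (1.24, adjusted exact p = 0.000949). Lower shares were found for E-boxes in general (60.3% against 66.6%, 0.763), GAGA repeats (2.19% against 3.77%, 0.570) and CA repeats (2.87% against 4.99%, 0.563). All of these had Benjamini-Hochberg adjusted p of at most 0.000949 by Fisher's exact test. Zelda (0.735, adjusted exact p = 0.196), the CTCF core (0.963, 0.653), the Su(Hw) core (1.21, 0.586) and the initiator (0.901, 0.0725) did not pass. Some of them did, with lower shares at summits, in other settings: within 200 bp of the summit the CTCF core (0.830, adjusted exact p = 0.00290) and the initiator (0.862, 0.00125), the initiator without replicate 1 (0.844, 0.0443) or 3 (0.8425, 0.0452), and both Zelda and the initiator in the own sets of replicate 1 (0.502, 0.0121 and 0.810, 0.00238) and 3 (0.554 and 0.863, both 0.0267). Against positions 500 bp away the initiator passed in the other direction, with a higher share at summits. The TATA box had an odds ratio of 1.51 (adjusted exact p = 3.17e-14) with this background and of 0.881 (0.0992) with 1 matched also on GC content; its call was also lost within 50 bp of the summit (1.02, 0.783). With that match, motif 6 (adjusted exact p = 0.149) and GAGA repeats (0.283) no longer passed; GAGA repeats also failed in set C (0.201) and against positions 500 bp away (0.116). The call for CAGCTG was lost among peaks in all 3 replicates (adjusted exact p = 0.357), without replicate 1, 2 or 3 (0.291, 0.112 and 0.238), in set A (0.196), in the stronger peaks (0.220) and within 200 bp of the summit (0.144).

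A search over all 7-mers, ranked on arms 2L, 3L and X and tested on 2R, 3R and 4, led back to CGATA and TATCGATA. Its first 7-mer contains CGATA and is itself part of TATCGATA, so the search does not tell these motifs apart. The first, ATCGATA, was within 50 bp of 427 of 1108 summits on the held-out arms (38.5%), against 2.03% of background peaks (odds ratio 30.3, 95% interval 25.4 to 36.3). The odds ratio was 16.3 against a background matched on GC content, 54.9 among peaks in all 3 replicates, and 49.7, 49.7 and 47.9 without replicate 1, 2 or 3. CTATCGA (27.7% against 1.25%) and ACTATCG (20.9% against 0.848%) came next. All 10 of the leading 7-mers passed on the held-out arms (Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p of at most 2.52e-57), with odds ratios from 11.8 to 31.0. They overlap each other and are not separate findings. ATCGATA was also first in each replicate's own set.

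Transfer RNA genes carried peaks more often than other genes. Of 277 testable tRNA genes, 160 (57.8%) had a conservative summit within 500 bp of a TSS, against 18.2% of the other genes (odds ratio 6.16, 95% interval 4.84 to 7.85, adjusted exact p = 2.82e-46). Fisher's exact test with Benjamini-Hochberg adjustment over 21 lists was used here and for the lists that follow. The strongest were tRNA:Leu-AAG-1-3 on 2R (signal 474), tRNA:Gly-TCC-1-2 on 3R (416.2), tRNA:Pro-CGG-2-3 on 3L (363.6) and tRNA:Ala-AGC-2-11 on 3R (337.1). These genes lie in clusters and share peaks: 118 peaks had a tRNA TSS in the window. Counted by peak, a comparison chosen after seeing the data, the shares were 4.72% and 0.136% of the background (odds ratio 36.4). Near-identical tRNA copies can share reads, which leaves the height of single peaks uncertain. Of 217 snRNA and snoRNA genes, 20 (9.22%) carried a peak, fewer than other genes (odds ratio 0.432, adjusted exact p = 0.000452). Split after seeing the data and not compared with each other, the snoRNA genes had 14 of 187 (7.49%, odds ratio 0.3445, 95% interval 0.1995 to 0.595) and the snRNA genes 6 of 30 (20%, 1.06, 0.435 to 2.61). A deficit was thus seen at the annotated starts of snoRNA genes, while the snRNA interval excludes neither a deficit nor an excess. Whether the annotated start of a snoRNA gene is a promoter of its own was not examined. The deficit therefore does not show that snoRNA promoters lacked peaks. Examples were snRNA:7SKa (signal 604.9), snoRNA:U3:54Ab, which shares the peak of tRNA:Leu-AAG-1-3 (474), snoRNA:Me18S-A1576 (327.1) and snoRNA:Psi18S-176 (276.9). That call was lost among peaks in all 3 replicates (adjusted exact p = 0.110) and without replicate 1 (0.0833) or 3 (0.0617).

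Genes for chromatin architecture were the list with the highest odds ratio. Of 16 testable genes for insulator and architectural proteins, 12 carried a peak (75%; odds ratio 12.9, 95% interval 4.17 to 40.1, adjusted exact p = 1.2e-05). SMC1, a cohesin subunit gene on 3R, had a signal of 617.8 at 58 bp from the TSS, and BEAF-32 itself, on 2R, 308.3 at 7 bp. Signals were 227.4 for pzg and 218.2 for Ibf1, whose peak lay in the 5' UTR of the neighbouring Ibf2. Ibf2 is also among the 12, with a best peak of the same signal, so the same peak counts for both genes. The test treated genes as independent. Of 15 zinc finger genes with a ZAD domain, a family of DNA-binding proteins, 6 carried a peak (odds ratio 2.87, unadjusted exact p = 0.0476, adjusted exact p = 0.125). These included wek (signal 229.7), pita (208.7), dwg (207.1) and grau (149.8); pita and dwg are also in the insulator list.

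Genes for protein synthesis and turnover followed. Of 78 cytosolic ribosomal protein genes, 35 carried a peak (44.9%; odds ratio 3.53, adjusted exact p = 2.18e-06), led by RpL32 (signal 826.5), RpS2 (572.4), RpS30 (452.2) and RpL36A (293). Of 35 proteasome genes, 17 did (48.6%; 4.08, adjusted exact p = 0.000343), led by Rpn6 (851.8), Prosalpha7 (494.6), Rpn10 (325.7) and Rpn2 (199.6). Of 70 mitochondrial ribosomal protein genes, 26 did (37.1%; 2.55, adjusted exact p = 0.00112), led by mRpL30 (473.4), mRpL17 (369.6), mRpL4 (358.8) and mRpL33 (337.4). Of 29 cell cycle and replication genes, 12 did (41.4%; 3.04, adjusted exact p = 0.0196), including CycB (536.1), Cdk2 (309.8), aurA (257.2) and E2f2 (253.2). The call for mitochondrial ribosomal protein genes was lost among peaks in all 3 replicates (adjusted exact p = 0.241), without replicate 1 (0.413) or 3 (0.170), and in the stronger peaks (0.0853). The cell cycle call was lost among those shared peaks (0.0665), without replicate 1, 2 or 3 (0.0851, 0.115 and 0.0644), with a TSS window of 250 bp (0.0577), with protein-coding TSSs only (0.0765) and against random lists matched on the number of TSSs (0.0816). Nor did the cell cycle list pass in the own sets of replicates 1, 2 and 3 (odds ratios 2.68, 2.53 and 1.27, adjusted exact p = 0.0722, 0.1265 and 0.8125).

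No list of developmental regulators passed the test. A peak was found at 1 of 13 gap and pair-rule genes (odd, signal 92.5), 1 of 7 Hox genes (abd-A, 99.4), 1 of 13 dorsoventral genes (sog, 85.8) and 1 of 17 mesoderm and muscle genes (Mef2, 61.9). It was found at 0 of 9 endoderm and gut genes, 3 of 15 neural and glial genes (brat 184.1, pros 92.4, insc 82.2) and 2 of 11 germline and piRNA genes (tud 264.6, gcl 89.4). The peak near tud had its summit in tRNA:Gly-GCC-1-13, 438 bp from the tud TSS. Segment polarity genes had peaks at 4 of 9 (wg 87.2, inv 83.6, arm 83.1, en 44.4; odds ratio 3.44, adjusted exact p = 0.167). With a TSS window of 250 bp they had 4 of 6 (7.67, 95% interval 1.41 to 41.9, unadjusted exact p = 0.0192, adjusted exact p = 0.0575), and in sets A and B 1 of 9. Among peaks in all 3 replicates, and without replicate 1, 2 or 3, they had 0 of 8 (odds ratios from 0.425 to 0.520, below 1); the peak at inv was overlapped in 1 replicate and those at the others in 0. The odds ratios of the other 7 lists in this paragraph ran from 0.226 to 1.07, with adjusted exact p of at least 0.394. These lists are small, and their intervals do not exclude sizeable differences: that of the neural list ran from 0.303 to 3.81.

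The remaining lists also did not pass. Of 71 respiratory chain and ATP synthase genes, 18 carried a peak (odds ratio 1.46, adjusted exact p = 0.359), led by UQCR-14 (383.6), ND-B14.5A (356.8), COX6B (286.6) and COX7A (274.9). In set C this list passed (odds ratio 2.09, adjusted exact p = 0.00961). Of 17 heat shock genes, 4 did (1.32, adjusted exact p = 0.763): DnaJ-1 (373.9), Hsc70-5 (169), Hsp83 (165.3) and Hsp60A (109.6). The counts were 1 of 10 for E(spl) complex genes (E(spl)m7-HLH, 59.1; adjusted exact p = 0.816), 0 of 5 for histone genes (0.776) and 1 of 10 for the genes chosen as negative controls, meant to be specific to testis or late muscle (dhd, 48.8; 0.816). That gene, for a thioredoxin of the female germline, was put in this list by mistake. Only 5 of the 111 histone genes in the annotation were testable, so their count says little about that list.

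**Figure D4:**
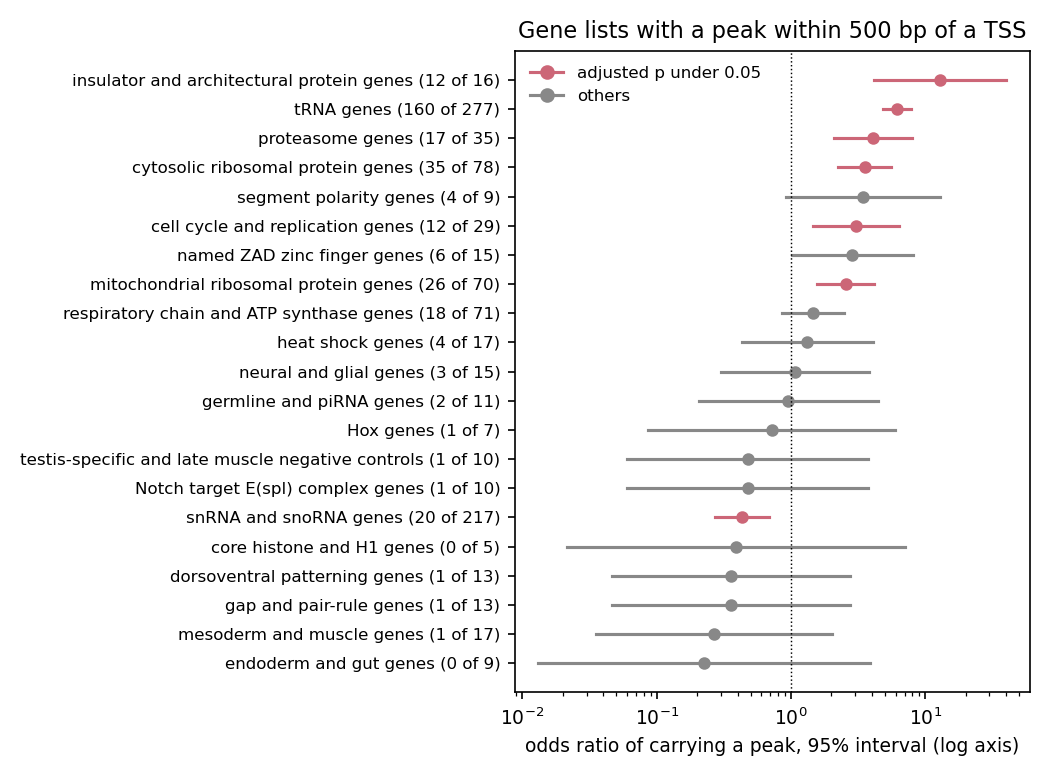
Points give the odds ratio of carrying a conservative summit within 500 bp of a TSS for each of 21 gene lists against all other testable genes, on a log axis, with 95% intervals as lines; the numbers are genes with a peak and testable genes. The 7 lists with an adjusted p under 0.05 are in red: insulator and architectural protein genes are highest at 12.9, and snRNA and snoRNA genes, at 0.432, are the only called list below 1. Whether that deficit holds for the snRNA genes alone is not settled.

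Promoter peaks were stronger than peaks elsewhere. The median signal was 144.5 for 2129 promoter peaks and 87.5 for 342 others on the assembled arms, a difference of 57.0 (permutation test, two-sided p = 1e-05, the smallest possible). In each replicate's own list the promoter median was also higher, by 20.2, 17.2 and 20. Peaks and genes are not independent replicates, so p-values over them describe these lists and do not measure the spread between embryo collections.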

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

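The tests on snRNA genes and signal were chosen only after the pattern they bear on was seen, as was the use as a test of the background matched on GC content, itself an alternative fixed in advance, and as were the comparisons of all tRNA peaks and of tRNA genes far from other genes, the comparisons of tRNA genes by shared stretches of sequence and of peaks with any close neighbour, and the comparisons of weak peaks with other positions near strong ones; the other tests were written down before their outcome was known. There were 117 ranked peaks with a score at or above the lowest in the conservative set that this set leaves out, with a median signal of 111; 54 lay in promoter windows, 42 on 3R and 28 outside the assembled arms. A further 28 conservative peaks lay on 26 unlocalised sequences assigned to X, the strongest with a signal of 322.3, and 2 of them were overlapped in all 3 replicates. Peaks outside the arms take no part in the comparisons of promoters, motifs and genes, while the left-out peaks on the arms stay in the background.

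Transfer RNA genes carried peaks more often than other genes. An origin in promoters of neighbouring genes with CGATA is argued against: of all 118 peaks with a tRNA TSS, 22.9% held CGATA, against 76.6% of peaks with none (odds ratio 0.0905, 95% interval 0.0583 to 0.1405, Fisher's exact test), and 99 of 183 tRNA genes more than 1 kb from the TSS of any other gene carried a peak (odds ratio 5.31, 3.96 to 7.12). The test written in advance took only the 97 peaks with a tRNA TSS and no other TSS in the window. Of these 19.6% held CGATA (odds ratio 0.0743, 0.0446 to 0.124), which met its bound. That choice of peaks selects against the explanation, so all tRNA peaks were used in its place after the values were seen. An excess common to all small RNA genes is argued against too, since tRNA genes exceeded the pooled snRNA genes (odds ratio 5.47, 95% interval 2.17 to 13.8). The 6 of 30 snRNA genes with a peak were snRNA:7SKa, snRNA:U1:95Ca, snRNA:U5:63BC, snRNA:U6:96Aa, snRNA:U6:96Ab and snRNA:U6:96Ac. Kinds of snRNA gene were not compared with each other, so an excess limited to tRNA genes and some of these kinds stays open. Reads shared between near-identical copies stay open: genes whose sequence occurs once still carried peaks at 20 of 53 (odds ratio 2.73 against non-tRNA genes, 1.57 to 4.77), which met the bound set in advance, but 49 of these 53 share at least 30 bp with another tRNA gene, so that bound did not isolate the explanation, and genes in several copies carried peaks more often still (62.5%; odds ratio 2.75 against single-copy genes). Of the 4 genes with no such stretch 0 carried a peak, which is too few to decide; no biological explanation was tested.

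The CGATA core was enriched at summits. Base composition is argued against by the odds ratio of 8.10 against a background matched on GC content, and the make-up of promoters by the odds ratio of 2.51 (95% interval 2.02 to 3.13) among peaks away from promoters, as explanations of the whole excess; the smaller value there leaves room for a part played by promoters. A feature of open chromatin unrelated to the amount of precipitated DNA stays open. The median signal was higher by 61.3 in peaks with CGATA. Score and signal were moderately correlated over the whole ranked list (Spearman correlation 0.539), and the conservative peaks are those of high score. The signal comparison may therefore restate part of the enrichment. How far it does so within the conservative set was not tested. Whether these sites would also be recovered with an antibody against GFP from embryos without the tag was not tested, since no control samples were analysed here. Binding of the tagged protein at CGATA, directly or through another protein, is therefore a hypothesis that the data do not tell apart from a common recovery of such promoters.

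Peaks of low signal passed the authors' threshold: 75 conservative peaks had a signal under 20, against a median of 132.6. A candidate explanation is that they are shoulders of stronger peaks, since 100% of them lay within 500 bp of a stronger conservative peak, against 4.08% of the other peaks; 11.2% of the others had any conservative neighbour that close. Background calls without CGATA are argued against, by a narrow margin, by the odds ratio of 1.76 (95% interval 1.08 to 2.87, Fisher's exact test, p = 0.0312). Closeness to a stronger peak is argued against as the whole source of that excess, again by a narrow margin. CGATA lay at 40% of these peaks, against 28.8% of positions as far from other conservative summits and of the same promoter class. That odds ratio was 1.65 (1.01 to 2.69, Fisher's exact test, unadjusted p = 0.0475). Positions as far on the other side of the same stronger summit held CGATA at 14.7% (3.88, 1.76 to 8.54), in a test that ignored their pairing with the peaks. These positions were set by distance and not drawn by promoter class. They held CGATA less often than the 28.8% above, so the larger odds ratio may reflect unlike positions. No biological explanation was tested.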

How the results depend on the processing

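No paired analysis was possible because there is 1 group. Over all alternatives, 84 values that answer a comparison kept their direction and their side of the threshold, or stayed within 1.5 times or 1 SD, and 6 moved. The promoter odds ratio, the excess in signal at promoters, and the counts of called classes, arms, motifs and 7-mers were among those kept, under every alternative run for them. For arms this holds for the count only: among peaks in all 3 replicates X and sequences outside the arms were called in place of chromosome 4 and the Y. The shared peaks fell from 1083 to 575 with only the peaks of each replicate above its median signal, as fewer peaks entered, and the mean pairwise overlap from 73.8% to 66.5% with reciprocal overlap of 50%, a stricter rule. Called gene lists went from 7 to 4 among peaks in all 3 replicates and to 4 with protein-coding TSSs. The latter setting leaves out tRNA, snRNA and snoRNA genes, and the cell cycle call was also lost in it. Without each replicate in turn, 4 to 6 were called. Leaving one out kept the conservative peaks found in both others, 1167 to 1333 of 2499, whose signal still includes its reads, so a shorter list and the missing replicate cannot be separated there. Of the values for single classes, arms, motifs and lists, 501 kept direction and call, 38 lost and 26 gained a call, and 40 turned direction. Of the called values only chromosome 4 (0.538 with random positions; 0.939 to 1.70 without each replicate) and the TATA box (0.881 matched on GC content) turned. The other turns were in items never called in the conservative set, as odds ratios. Arms: 2L 0.984 in set B and 0.975 to 1.02 without each replicate; X 0.970 in set C. CTCF core: 1.04 in set C, 1.09 in a 50 bp window, 1.25 matched on GC content and 1.10 against positions 500 bp away. Su(Hw) core: 0.571 in the stronger conservative peaks (signal above the median), 0.740 in all 3 replicates, 0.588 in a 50 bp window, 0.666 matched on GC content, 0.889 against positions 500 bp away, and 0.605 to 0.909 without each replicate. Initiator: 1.16 against positions 500 bp away (adjusted exact p = 0.0361). Segment polarity genes: 0.599 in set A, 0.574 in set B, 0.438 in the stronger peaks, 0.520 in all 3 replicates, and 0.425 to 0.486 without each replicate. Neural and glial genes: 0.850 in set C, 0.572 in the stronger peaks, 0.680 in all 3 replicates, 0.958 and 0.961 with windows of 250 and 1000 bp, 0.918 with protein-coding TSSs, and 0.556 to 0.636 without each replicate. Set B gave 1.02 for germline genes, and set C 1.48 for Hox and 1.05 for endoderm genes. The 250 bp window gave 0.884 for heat shock genes and the 1000 bp window 1.85 for the negative controls. Except where said, the cause was not tested. Depth is unknown, so its effect on weak peaks was not measured. Settings without peaks of signal under 20, chosen after seeing the data, turned no direction; the initiator gained a call (0.889).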

Other observations

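Beyond the comparisons above, 641 conservative peaks on the arms held no CGATA within 100 bp, and 91 of them had a tRNA TSS within 500 bp. In these peaks a 7-mer search, ranked on 2L, 3L and X and chosen after the CGATA result was seen, gave 10 leading 7-mers, all of which passed on the held-out arms. GGTTCGA, part of the internal promoter of tRNA genes, was at 11.8% of held-out summits against 0.852% of background peaks without CGATA (odds ratio 15.6, Fisher's exact test), and 49 of the 54 peaks with it had a tRNA TSS in the window. TAGTCGA, at 6.71% against 0.682% (odds ratio 10.5), was mostly away from tRNA genes, which held 1 of its 41 peaks, and so was GATACCC (4.15% against 0.648%, odds ratio 6.65; 1 of 28). TATCAGA, ACTATCA and CTATCAG had 0 of 35, 0 of 37 and 0 of 31 peaks at a tRNA TSS. ACTATCA differs only in its last base from ACTATCG, a leading 7-mer over all conservative peaks. Some of the 10 overlap each other, and they were not sorted further, so near matches of CGATA were not set apart. Within the conservative set, 89.3% of the 618 peaks with the highest signal held CGATA and 97.1% lay at promoters, against 49.6% and 71.1% of the 617 with the lowest.

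A hypothesis written before its test was that promoter peaks with CGATA lie between divergently transcribed genes more often than promoter peaks without it. Of 1700 such peaks with CGATA, 951 (55.9%) lay between TSSs pointing away from each other, each within 1 kb of the summit, against 174 of 429 (40.6%) without it. The odds ratio was 1.86 (95% interval 1.5 to 2.31, Fisher's exact p = 1.22e-08), in the direction of the hypothesis. Peaks at tRNA genes were unevenly split: 91 of the 429 without CGATA had a tRNA TSS within 500 bp, against 27 of the 1700 with it. They were not set apart, so their part in the odds ratio was not tested. Among background promoter peaks the share was 22.9%. Gene density may add to this difference and was not tested apart from the odds ratio of 1.86.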
